A study of Bos taurus with 16 samples.

How the data were processed

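Total RNA of corpora lutea from 16 Japanese Black cows, 4 animals per group, was labelled with Cy3 after linear amplification and hybridised to 1-colour custom bovine oligonucleotide arrays with 15744 features, per the labels' protocols. The groups were cyclic cows on days 10-12 and pregnant cows on days 20-25, 40-45 and 150-160, per the labels. Per the submitters' processing notes the scans were read with Agilent Feature Extraction 9.5. The deposited processed signal is an intensity on a linear scale: per the file headers it is the mean signal with background and spatial trend subtracted, with a surrogate in place of signals not above their error and no scaling between arrays. The deposited value table of the series is on a log2 scale. Set against the scanner values, each of its columns equals log2 of the processed signal minus a constant close to the log2 75th percentile of that array, with a largest departure of 0.0046. Its column medians lie between -3.18 and -2.98. That table was used as an alternative only.

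Of each array 536 control spots were left out, leaving 15208 probes, and 220 spots with outlier flags, over all arrays, were set to missing. Values are log2 of the processed signal minus the 75th percentile of log2 processed signal of that array. A probe was tested when it was well above background and free of outlier flags on at least 3 of the 4 arrays of at least 1 group, which held for 11941 probes. For 1 of these a group had no value, so 11940 entered the comparisons of days 150-160 and the F test. Probes not well above background on every array of a group have only a bound there: the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Probe names in the scanner files are those of the array design. A table of RefSeq genes of the assembly ARS-UCD2.0 was used for names alone: 2496 probes were named through an accession, 1984 through a gene ID, 1578 through a symbol or synonym and 1166 through a human gene named in the description, 100 kept the name in the file, and 7884 have no symbol. The 7324 probes with a symbol stand for 6992 symbols, 228 of them with more than 1 probe. Of the probes tested 6193 had a symbol and 5748 had none.

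Comparisons were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with all 16 arrays and group as the term, 12 residual and 2.77 prior degrees of freedom, and Benjamini-Hochberg adjustment over the probes tested. A probe was called at an adjusted p under 0.05, and the number also changed at least 2-fold was counted. The 6 comparisons were each pregnancy stage against cyclic cows and each later stage against each earlier one, with a moderated F test over the groups. All tests were two-sided. In 33 gene lists a gene was represented by its probe with the highest mean signal, which gave 5919 genes, and missing values were replaced by the group mean. The 30 lists with at least 5 tested genes were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 90 pairs of list and comparison; camera with an estimated correlation and fry were alternatives. The lists covered steroidogenesis, cholesterol, prostaglandins, interferon-stimulated genes, chemokine ligands and receptors, cytokines, complement, MHC class II, markers of immune, vascular, follicular, matrix and red blood cells, angiogenic and vasoactive factors, proteases, apoptosis, proliferation, the IGF system, hormones, energy metabolism, antioxidant enzymes, stress and immediate early genes, and ribosomal proteins. Numbers of genes called in several comparisons were set against 100 simulations of unchanged groups, independent lists and cyclic arrays split between the comparisons. In each simulation the comparisons shared 4 simulated cyclic arrays, made like the other groups from the shuffled residuals of all 16 arrays. Scores of lists, the mean over genes of the deviation from each gene's mean, were compared with exact permutation tests, and the lists singled out were also set against the largest score difference of any list in each split, a test chosen after the results were seen, as was the floor applied to the granulocyte scores.

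Named genes followed a rule. Against cyclic cows these were the 10 largest rises and 10 largest falls among called probes with a symbol whose groups did not overlap, 1 probe per gene, up to 4 members with the smallest adjusted p of each list called or with at least 3 called members, and in every comparison STAR, CYP11A1, HSD3B1, LHCGR, PTGFR, OXT and each tested chemokine ligand and receptor. Between stages they were the 5 largest rises and 5 largest falls. Of 38 chemokine genes on the array 26 were tested. Called members named beyond the rule were chosen after their values were seen. Apart from the exceptions that follow, the groups, tests, lists, naming rule and alternatives were chosen before the data were examined. Slide as a block without replicate 4 of days 20-25, the granulocyte floor and the list tests between stages were chosen after seeing the data. So were the tests of the choice among the gene lists, immune cells, slide, granulocyte number, single arrays and stress, and the choice of probes without a gene name.

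Alternatives were median scaling, quantile normalization, normexp background correction (offset 50) with quantile normalization or the 75th percentile, the deposited value table, no filter on dim probes, a filter requiring all arrays, a floor at the lowest signal well above background, spots with outlier flags kept, slide as a block, each slide alone, the replicate number as a block, a fit of the compared groups alone, trended and robust variances, array weights, other thresholds, genes in place of probes, and leaving out each array in turn. The tests were run first on simulated data of 11941 probes with 200 changed probes in each of 5 sets. At a log2 change of 1 limma called 60%, 52.5% and 60% of changed probes in the comparisons of days 20-25, 40-45 and 150-160 with cyclic cows, at 2 it called 90.3%, 89.1% and 89.7%, and at 0.5 it called 8.36%, 10.7% and 12.5%, with 5.05%, 5.07% and 5.77% of its calls false. Camera called a simulated shift of 0.5 of the interferon-stimulated list on days 20-25 in 5 of 5 sets, and 0 of 445 other list tests. The simulated probes varied independently, while the estimated correlation of that list in the real data was 0.338. The simulation therefore gives no rate of false calls for lists of correlated genes. Data handling used the R package data.table, version 1.17.8, and Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Genome coordinates were not used here, and 1 gene that the naming rule selects is not reported here.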

Results

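RNA from the corpus luteum, the progesterone-secreting gland that forms in the ovary after ovulation, was measured in 16 Japanese Black cows on 1-colour bovine arrays. The labels give 4 groups of 4 separate animals: cyclic cows on days 10-12 of the estrous cycle, and pregnant cows on days 20-25, 40-45 and 150-160 of gestation, with the day of insemination as day 1. The series asks how gene expression in this gland differs between the cycle and pregnancy, with chemokines as a stated interest. The 75th percentile of the processed signal lay between 2020 and 4288 per array, and 71.9% to 79.6% of the probes were well above background. The arrays lay on 2 slides, each holding 2 arrays of every group. Array position within the slide was tied to the group, so position and group cannot be told apart. Glands of pregnant cows were taken on later days than cyclic ones, so gland age and pregnancy cannot be told apart either. The number of arrays per group, 4, limits the precision of every value. Levels are log2 signals relative to each array's 75th percentile, given as mean ± SD over n = 4 cows.

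Along the first principal component, which held 21.8% of the variance, cyclic cows lay between -45.5 and -14.3, days 20-25 between -27.8 and 4.3, days 40-45 between 11.6 and 12.9, and days 150-160 between 29.6 and 33.7. The second component held 16.1% and set 1 array apart, replicate 4 of days 20-25, at -77.7. The mean correlation of that array with the rest of its group was 0.962. The median SD over probes was 0.302 in cyclic cows, 0.248 on days 20-25, 0.207 on days 40-45 and 0.305 on days 150-160. Replicates 1 and 2 of days 20-25 were the most alike pair (r = 0.992 over probes) and shared 0 identical values, so they were kept as separate samples. The moderated F test of limma found 460 of 11940 probes to differ among the 4 groups at the adjusted threshold. With slide as a block the number was 680, and within slide 1 and slide 2 it was 42 and 12. It was 301 without cyclic replicate 4 and 267 without days 150-160 replicate 2.

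**Figure D1:**
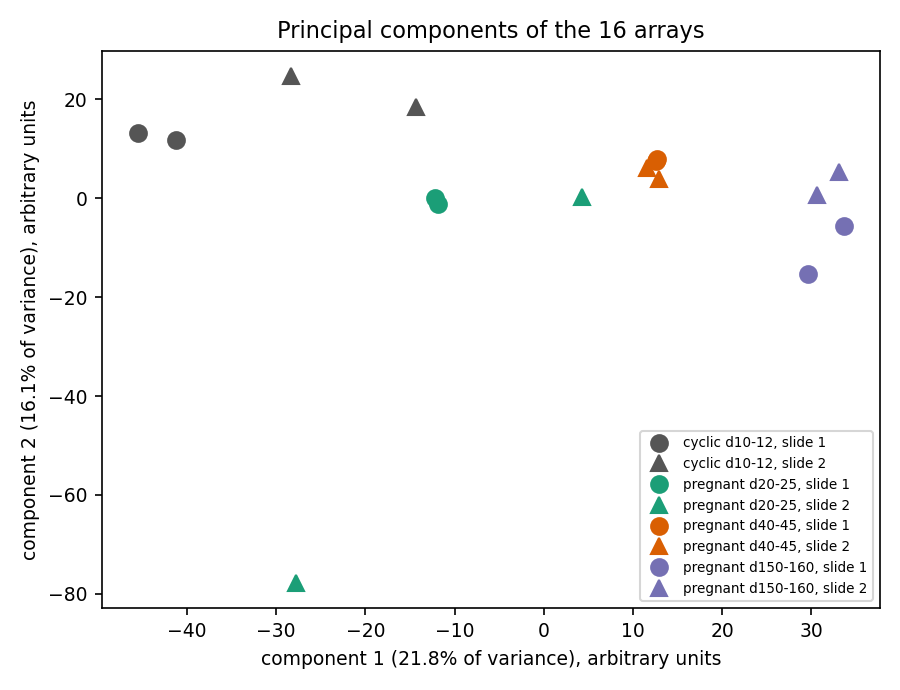
Scores of the 16 arrays on the first and second principal components of the tested probes, in arbitrary units, with colour for the group, circles for slide 1 and triangles for slide 2. Replicate 4 of days 20-25 lies at -77.7 on the second component, away from the other arrays.

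On pregnancy days 20-25 a small set of genes differed from cyclic cows. Among the falls were those of antimicrobial peptide genes of granulocytes. CATHL4, a cathelicidin, fell from -5.33 ± 0.85 to -8.70 ± 0.42, a log2 change of -3.37 (SE 0.33, adjusted p = 0.00031). Among the genes that rose were SOCS2, a suppressor of cytokine signalling, IGFBP6, an insulin-like growth factor binding protein, and FGF1, a fibroblast growth factor.

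SOCS2 rose from -0.09 ± 0.30 to 1.28 ± 0.48, a log2 change of 1.37 (SE 0.23, adjusted p = 0.0302). IGFBP6 rose by 1.19 (SE 0.20, adjusted p = 0.0297) and FGF1 by 1.05 (SE 0.19, adjusted p = 0.0315). The rises of largest size among named genes were those of SLC26A10, a member of an anion transporter family, at 1.79 (adjusted p = 0.0292), KCNT2, a sodium-activated potassium channel, at 1.56 (adjusted p = 0.0297), and LMCD1, a LIM domain protein, at 1.55 (adjusted p = 0.0458). PLAC8 rose by 1.31 on 1 probe (adjusted p = 0.0369), while its other probe gave -0.25. PDE6G, ATP6V1B2 and WASL rose by 1.20, 1.17 and 0.84. CATHL1 and CATHL3 changed by -2.52 and -2.24 (adjusted p = 0.0292 and 0.0308), the beta-defensin gene BNBD-5 by -2.48 (adjusted p = 0.0246), and CHGB, the secretory granule protein chromogranin B, by -2.14 (adjusted p = 0.0183). PLAAT1, a phospholipase and acyltransferase, changed by -3.66 (adjusted p = 0.0458) and PRPS1, which makes phosphoribosyl pyrophosphate, by -0.67 (adjusted p = 0.0315). Where a gene was not well above background on any array of a group, its fold is a bound, from the bright group's mean against the lowest signal well above background. On this basis CATHL4 was at least 2.53-fold and CATHL1 at least 2.31-fold lower, and no fold is given for CATHL3. With every value under background raised to it, the falls of CATHL4, CATHL1 and CATHL3 did not pass (adjusted p = 0.0887, 0.165 and 0.537). On days 20-25 CHGB and PLAAT1 were well above background on 2 of 4 arrays and BNBD-5 on 1 of 4.

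Interferon-stimulated genes were the list with the smallest p on days 20-25. Of 23 tested members 22 had a positive change, with a median of 0.80, and camera called the list higher (adjusted p = 5.94e-10; adjusted p = 0.672 with an estimated correlation). No member passed over all genes, while 14 passed when adjusted over the list alone. LGALS9, a galectin, was 1.23 higher (adjusted p = 0.0616), IFITM3, an antiviral membrane protein, 1.12 (adjusted p = 0.0616), DHX58, an RNA sensor regulator, 1.02 (adjusted p = 0.096) and EIF2AK2, the RNA-activated kinase PKR, 0.62 (adjusted p = 0.0633). The list median was 1.15 within slide 1 and 0.44 within slide 2, and its adjusted p with slide as a block was 1.68e-09.

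Endothelial cell markers had a median of 0.43 over 17 genes and were called higher by camera (adjusted p = 0.00117; adjusted p = 0.874 with an estimated correlation). No member passed over all genes and 5 passed when adjusted over the list alone; ENG, CD34, ROBO4 and ERG had changes of 0.81, 0.75, 0.70 and 0.57. The median was 0.39 and 0.46 within slides 1 and 2 (adjusted p = 0.00192 with slide as a block). Granulocyte markers had a median of -0.91 over 10 genes, or -0.88 with genes under background at their bound, and were called lower (adjusted p = 9.08e-08; adjusted p = 0.108 with an estimated correlation). The cathelicidins CATHL1, CATHL3 and CATHL4 were the 3 members that fell over all genes, 4 fell when adjusted over the list alone, and CATHL2 had a change of -0.88 (adjusted p = 0.247). Within slides 1 and 2 the median was -1.05 and -1.04 (adjusted p = 4.36e-07 with slide as a block).

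Oxidative phosphorylation genes, which encode subunits of the respiratory chain and ATP synthase, had a small negative median of -0.15 over 50 genes (camera adjusted p = 5.8e-06; adjusted p = 0.874 with an estimated correlation). Of these, 45 had a negative change and 0 passed over all genes or adjusted over the list alone; ATP5MC1, ATP5ME, COX7B and NDUFS7 had changes of -0.38, -0.33, -0.31 and -1.02. The median was -0.10 and -0.20 within the slides (adjusted p = 4.36e-07 with slide as a block). Genes of cholesterol synthesis and uptake had a median of -0.22 over 18 genes (camera adjusted p = 0.0215; adjusted p = 0.874 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone. MVK, HMGCS1 and ACAT2 had changes of -0.84, -0.46 and -0.63, and ABCA1, a cholesterol exporter, 0.72. This list was no longer called without cyclic replicate 1 or 4 or days 20-25 replicate 1 or 4, with adjusted p up to 0.194. With slide as a block and without days 20-25 replicate 4 its median was -0.07 (adjusted p = 0.262). With all arrays its median was -0.27 and -0.19 within the slides (adjusted p = 0.0475 with slide as a block), and it was not called within slide 2 (adjusted p = 0.166).

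In all, limma called 35 of 11941 probes on days 20-25 against cyclic cows, 26 higher and 9 lower, of which 28 changed at least 2-fold and 19 had a gene symbol. The count was 78 with slide as a block, 3 within slide 1 and 6 within slide 2. The higher share was 74.3%, and 88.0% after normexp background correction with the 75th percentile. The count was 85 without cyclic replicate 1, 11 without cyclic replicate 2, 6 without cyclic replicate 4, 9, 4, 4 and 12 without days 20-25 replicates 1, 2, 3 and 4, and 55 without days 150-160 replicate 1. Of the calls of the genes named here that of CATHL4 stood without any 1 array, and the highest adjusted p of the others without 1 array lay between 0.0704 for CHGB and 0.139 for LMCD1.

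**Figure D2:**
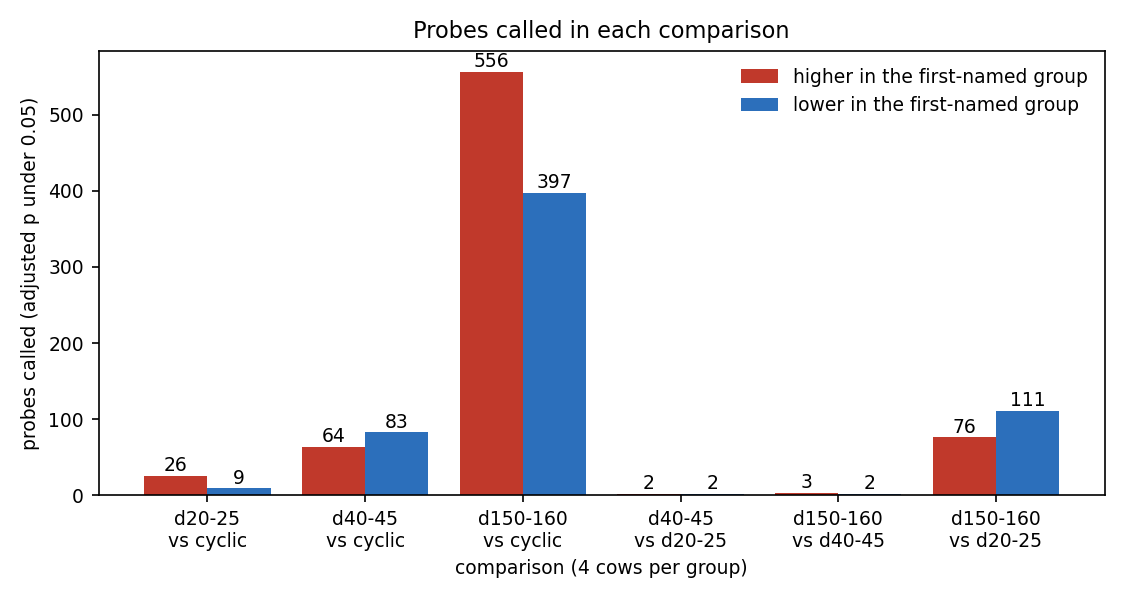
Number of probes called by limma in each of the 6 comparisons, with red bars for probes higher and blue bars for probes lower in the group named first, 4 cows per group. Days 150-160 against cyclic had 556 higher and 397 lower, against 26 and 9 for days 20-25.

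By days 40-45 the corpus luteum held far less oxytocin RNA and more RNA of a prostaglandin receptor and a chemokine. OXT, which encodes the luteal hormone oxytocin, fell from 5.80 ± 0.61 to 1.75 ± 0.67, a 16.5-fold difference (log2 change -4.05, SE 0.46, adjusted p = 0.000534). PTGER3, the prostaglandin E2 receptor EP3, rose from -6.45 ± 1.28 to -1.34 ± 0.46, a 34.7-fold difference (SE of the log2 change 0.51, adjusted p = 0.000132). CCL11, the chemokine eotaxin, was not well above background on any cyclic array and rose to -1.42 ± 1.68, at least 45.4-fold (adjusted p = 0.000667).

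Other large rises were those of B3GAT2, a glucuronyltransferase, at 3.32 (adjusted p = 0.0136), UPK1B, a uroplakin, at 3.20 (adjusted p = 0.0136), and ZBTB16, a zinc finger transcription factor, at 2.73 (adjusted p = 0.00563). SERPINA1, the protease inhibitor alpha-1-antitrypsin, rose at least 2.18-fold (adjusted p = 0.00708) and CLDN10, a tight junction claudin, at least 1.16-fold, being well above background on 2 of 4 pregnant arrays. ADAMTSL3, MAL and MIC1 rose by 2.46, 2.28 and 2.23. Among the falls, NPTX2, a neuronal pentraxin, changed by -6.25 (adjusted p = 0.00987). CD36, a scavenger receptor and fatty acid transporter, changed by -2.76 (adjusted p = 0.00563), PLAAT1 by -3.67 (adjusted p = 0.0223), the immunoglobulin gene IGG1C by -2.80 (adjusted p = 0.0223) and the defensin gene DEFB4A by -3.76 (at least 2.76-fold lower, adjusted p = 0.0243). ASIP, the agouti signalling protein, was at least 24.0-fold lower (adjusted p = 0.0223). Cyclic replicate 2 lay at -6.63 for ASIP and the other cyclic cows between -0.87 and -0.73, so this bound on means does not describe that cow. XCL1, the chemokine lymphotactin, changed by -3.42 (SE 0.65, adjusted p = 0.0181). NPTX2 was well above background on 1 of 4 pregnant arrays, and PTGER3, B3GAT2, CATHL3 and DEFB4A on 3 of 4 cyclic arrays.

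Granulocyte markers had a median of -1.33 on days 40-45, or -1.05 with genes under background at their bound, and were called lower by camera (adjusted p = 9.08e-08; adjusted p = 0.108 with an estimated correlation). CATHL1, CATHL3 and CATHL4 fell to under background, at least 2.58-fold, 1.08-fold and 2.84-fold, 7 of 10 members fell when adjusted over the list alone, and CATHL2 had a change of -0.94. With every value under background raised to it, CATHL4 still passed (adjusted p = 0.0393), while CATHL1 and CATHL3 did not (adjusted p = 0.0923 and 0.353), nor did DEFB4A, SERPINA1 and CLDN10 (adjusted p = 0.228, 0.103 and 0.379). The median was -1.60 and -1.32 within slides 1 and 2 (adjusted p = 4.36e-07 with slide as a block). Macrophage markers had a median of -0.61 over 15 genes (camera adjusted p = 0.00411; adjusted p = 0.874 with an estimated correlation). The lysosomal protein gene CD68 fell, by -1.32 (adjusted p = 0.0223), 3 members fell when adjusted over the list alone, and MRC1, AIF1 and FCGR1A had changes of -0.87, -1.04 and -1.44. The median was -0.67 and -0.36 within the slides (adjusted p = 0.00389 with slide as a block), and the adjusted p was 0.082 without cyclic replicate 2.

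Proliferation genes had a median of -0.46 over 19 genes (camera adjusted p = 0.00176; adjusted p = 0.874 with an estimated correlation). AURKB, a mitotic kinase, was the 1 member that fell, by -1.83 (adjusted p = 0.00744), over all genes and adjusted over the list alone; CCNB2, CENPF and PRC1 had changes of -1.31, -1.19 and -0.85. The list median was -1.20 within slide 1 and 0.23 within slide 2, so its direction held on 1 slide (adjusted p = 0.00283 with slide as a block, and 0.387 without cyclic replicate 1). Oxidative phosphorylation genes had a median of -0.16 (camera adjusted p = 0.00117; adjusted p = 0.96 with an estimated correlation), with 41 of 50 negative and 0 called over all genes or adjusted over the list alone. ATP5MC1, NDUFA2, COX7B and NDUFA9 had changes of -0.44, -0.38, -0.35 and -0.34. The list median was -0.13 and -0.20 within the slides (adjusted p = 0.000243 with slide as a block). The list was not called within slide 1 (adjusted p = 0.0738) or without cyclic replicate 4 (adjusted p = 0.0734).

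Cytokine genes had a median of -0.40 over 13 genes (camera adjusted p = 0.00345; adjusted p = 0.874 with an estimated correlation), with 0 called over all genes and 2 lower when adjusted over the list alone. IL1A, an inflammatory cytokine, and IL1RN, its receptor antagonist, had changes of -3.13 and -2.89 with cyclic SDs of 2.68 and 2.27, and IL1A was not well above background on any array of days 40-45; IL18 and IL16 had -0.73 and -0.54. The median was -0.54 and -0.43 within the slides (adjusted p = 0.00557 with slide as a block). Chemokine ligands had a median of -0.74 over 19 genes (camera adjusted p = 0.0457; adjusted p = 0.874 with an estimated correlation), with CCL11 higher and XCL1 lower over all genes and 2 higher and 6 lower when adjusted over the list alone. Their median was -0.03 within slide 1 and -1.41 within slide 2, the adjusted p with slide as a block was 0.0587, and the call was lost on leaving out any of 7 single arrays (adjusted p up to 0.268): cyclic replicates 2 and 4, days 20-25 replicates 1, 2 and 4, and days 40-45 replicates 3 and 4. Interferon-stimulated genes had a median of 0.08 on days 40-45 and were not called (adjusted p = 0.878), but their median was 0.56 within slide 1 and -0.46 within slide 2, each called (adjusted p = 2.92e-06 and 3.58e-05), so the slides went opposite ways.

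In all, limma called 147 probes on days 40-45 against cyclic cows, 64 higher and 83 lower, of which 119 changed at least 2-fold and 82 had a gene symbol. The count was 211 with slide as a block and 51 and 12 within slides 1 and 2. The count was 77, 226 and 82 without cyclic replicates 2, 3 and 4, 90 without days 20-25 replicate 2, and 64, 63 and 75 without days 40-45 replicates 1, 2 and 3. Without some single arrays the named calls of MAL, IGG1C, PLAAT1, DEFB4A, CD68, ASIP, MIC1 and XCL1 were lost, with highest adjusted p between 0.0657 for MIC1 and 0.133 for MAL.

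Days 150-160 showed the largest number of differences from cyclic cows. CCL11 rose to 2.33 ± 0.56 from below background, at least 608-fold (adjusted p = 7.61e-06), and PTGER3 rose 87.0-fold, by 6.44 (SE 0.51, adjusted p = 7.61e-06). OXT fell to -2.17 ± 0.98, a log2 change of -7.97 (SE 0.46, adjusted p = 3.44e-07). Of 26 matrix genes 9 fell and 1 rose, 3 of 19 proliferation genes fell, and 5 of 14 complement genes and 4 of 15 immediate early genes rose.

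Other large rises were those of ANXA8L1, an annexin, at 6.05 (adjusted p = 0.000637), PENK, the enkephalin precursor, 63.8-fold (adjusted p = 0.00251), and CLDN10, at least 9.17-fold (adjusted p = 2.09e-06). IGFBP2, an insulin-like growth factor binding protein, rose by 4.87 (adjusted p = 0.0126), with an SD of 2.48 among the pregnant cows, and B3GAT2 by 4.62 (adjusted p = 0.000384). NEFM, a neurofilament protein, DAPL1 and PPP2R2C, a phosphatase subunit, rose by 4.51, 3.95 and 3.91 (adjusted p = 0.00243, 9e-05 and 0.00208). Of the falls, NPTX2 changed by -6.07 (adjusted p = 0.0036), and XCL1 was 16.8-fold lower (log2 change -4.07, SE 0.65, adjusted p = 0.00215). PLAAT1 changed by -3.58 (adjusted p = 0.0081) and NDP, which encodes the Wnt receptor ligand norrin, by -3.25 (adjusted p = 0.0157). OPALIN, CYP11B1, an enzyme of corticosteroid synthesis, DEFB4A and CATHL4 were at least 4.52-fold, 2.23-fold, 2.1-fold and 2.16-fold lower, being under background on the pregnant arrays. On the pregnant arrays NPTX2 was well above background on 1 of 4 and PLAAT1 and NDP on 2 of 4. On the cyclic arrays NEFM, DAPL1 and ITGAM were so on 1 of 4, ANXA8L1 on 2 of 4, and PENK, PPP2R2C, CYP11B1, PLA2G4A and ESR2 on 3 of 4.

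Extracellular matrix and fibroblast markers had a median of -0.50 over 26 genes (camera adjusted p = 0.000358; adjusted p = 0.874 with an estimated correlation). Over all genes 9 fell and 1 rose, and adjusted over the list alone 11 fell and 2 rose. The collagen chain genes COL1A2 and COL4A1 changed by -2.72 and -1.09 (adjusted p = 0.00145 and 0.00363), fibronectin, FN1, by -1.95 (adjusted p = 0.000341) and SPARC, a matrix glycoprotein, by -0.78 (adjusted p = 0.0224). The median was -0.74 and -0.40 within slides 1 and 2 (adjusted p = 0.00192 with slide as a block). Proliferation genes had a median of -0.91, or -0.86 with genes under background at their bound (camera adjusted p = 8.81e-06; adjusted p = 0.874 with an estimated correlation). AURKB, the cyclin gene CCNB2 and the spindle protein gene PRC1 fell, by -2.44, -2.00 and -1.74, and 11 of 19 fell when adjusted over the list alone; NUSAP1 had a change of -1.20 (adjusted p = 0.0509). The median was -1.74 within slide 1 and -0.19 within slide 2, where the list was not called (adjusted p = 0.101; adjusted p = 1.67e-05 with slide as a block).

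Complement genes had a median of 0.65 over 14 genes (camera adjusted p = 0.00117; adjusted p = 0.874 with an estimated correlation), and 5 rose over all genes, among them C1R and C1S, proteases of the classical pathway, at 1.34 and 1.01, and the inhibitors SERPING1 and CD59 at 1.41 and 1.12. Adjusted over the list alone 5 rose and 1 fell, and the median was 0.82 and 0.27 within the slides (adjusted p = 0.00058 with slide as a block). Immediate early genes, which respond fast to growth factors and stress, had a median of 1.04 over 15 genes (camera adjusted p = 0.000228; adjusted p = 0.874 with an estimated correlation). CCN1, DUSP1, EGR1 and GADD45B rose, by 2.40, 1.86, 1.09 and 1.04, and 9 rose when adjusted over the list alone; the heat shock list, which also responds to stress, had a median of 0.33 (adjusted p = 0.0642). The immediate early median was 1.55 and 0.52 within the slides (adjusted p = 0.000313 with slide as a block). Endothelial cell markers had a median of 0.37 (camera adjusted p = 0.009; adjusted p = 0.874 with an estimated correlation). The vascular growth factor receptor gene FLT1, ENG and the angiopoietin receptor gene TEK rose, by 1.42, 1.13 and 0.85, 7 of 17 rose when adjusted over the list alone, and ESAM had a change of 0.65 (adjusted p = 0.0535). The list median was 0.73 and 0.18 within the slides (adjusted p = 0.0114 with slide as a block), and the adjusted p was 0.195 without days 150-160 replicate 1. The list was not called within slide 2 (adjusted p = 0.507) or with array weights.

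Granulocyte markers had a median of -0.80, or -0.58 with genes under background at their bound (camera adjusted p = 0.00141; adjusted p = 0.741 with an estimated correlation). CATHL1, CATHL3 and CATHL4 fell to under background, over all genes and adjusted over the list alone, CATHL1 at least 1.97-fold and CATHL3 with no fold given, and PGLYRP1 had a change of -1.57 (adjusted p = 0.258). The median was -0.97 and -0.62 within the slides (adjusted p = 0.00265 with slide as a block), and the list was not called with every value under background raised to it (adjusted p = 0.0546). On that basis CATHL4 still passed (adjusted p = 0.0479), while CATHL1 and CATHL3 did not (adjusted p = 0.126 and 0.88), nor did DEFB4A, CYP11B1 and OPALIN (adjusted p = 0.235, 0.173 and 0.0836). Oxidative phosphorylation genes had a median of -0.26 with 46 of 50 negative (camera adjusted p = 1.48e-05; adjusted p = 0.874 with an estimated correlation). NDUFA9 fell, by -0.43 (adjusted p = 0.0431), 0 passed when adjusted over the list alone, and ATP5MC1, NDUFA2 and ATP5ME had changes of -0.44, -0.48 and -0.42; the median was -0.37 and -0.13 within the slides (adjusted p = 1.39e-06 with slide as a block).

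Several lists that camera did not call held members that moved both ways on days 150-160. Of 19 prostaglandin genes 4 rose and 2 fell, with 4 higher and 4 lower when adjusted over the list alone. PTGFR, the receptor of the luteolytic prostaglandin F2 alpha, rose by 0.85 (adjusted p = 0.0221) and SLCO2A1, a prostaglandin transporter, by 1.39 (adjusted p = 0.00491), and AKR1B1, a prostaglandin F synthase, changed by -0.93 (adjusted p = 0.00471). PLA2G4A, the cytosolic phospholipase A2, changed by -1.50 with values under background in pregnancy, and by 0.06 when those were raised to it. Of 11 genes of the IGF system 4 rose and 2 fell, over all genes and adjusted over the list alone: IGFBP6 and PAPPA, a protease of IGF binding proteins, rose by 1.91 and 0.75, and IGF2 changed by -2.01 (adjusted p = 0.00208). Of 15 macrophage markers the integrin gene ITGAM and the oxidase gene CYBB rose, by 3.91 and 1.38, and CD68 and the mannose receptor gene MRC1 fell, by -1.57 and -1.03, with 3 higher and 5 lower when adjusted over the list alone. Of 16 hormone and receptor genes PRLR, the prolactin receptor, rose by 2.71 (adjusted p = 0.0104), and OXT and ESR2 fell, with the same numbers when adjusted over the list alone. ESR2, an estrogen receptor, changed by -2.18 and by 0.06 with values under background raised to it, and THRA had a change of 0.37. Of 18 apoptosis genes FAS rose by 1.28, and BAK1 and CASP6 changed by -0.88 and -0.80, with 3 higher and 5 lower when adjusted over the list alone; BCL2 had -0.78 (adjusted p = 0.0525).

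In all, limma called 953 probes on days 150-160 against cyclic cows, 556 higher and 397 lower, of which 512 changed at least 2-fold and 486 had a gene symbol. The count was 1185 with slide as a block and 250 and 21 within slides 1 and 2. The count was 582 without cyclic replicate 4 and 580 without days 150-160 replicate 2. Of the 58 calls of genes selected for naming 45 stood without any 1 array. All 58 had the same direction within both slides, but the size could differ. Within slides 1 and 2 the change was 4.3 and 1.12 for PRLR, 1.38 and 0.32 for PTGFR, and 2.2 and 0.64 for FLT1. Other changes were larger within slide 2, such as 1.84 and 1.97 for IGFBP6 and 1.09 and 1.58 for C1R. The call of NDUFA9 was lost on leaving out any of 13 single arrays and that of GADD45B any of 11, with highest adjusted p of 0.115 and 0.0971. CCN1, TEK, CYBB, CXCL12, CATHL1, PTGFR, EGR1, MRC1, SPARC, PRC1 and NDP were lost without some single arrays, with highest adjusted p between 0.0502 for NDP and 0.102 for CCN1.

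**Figure D3:**
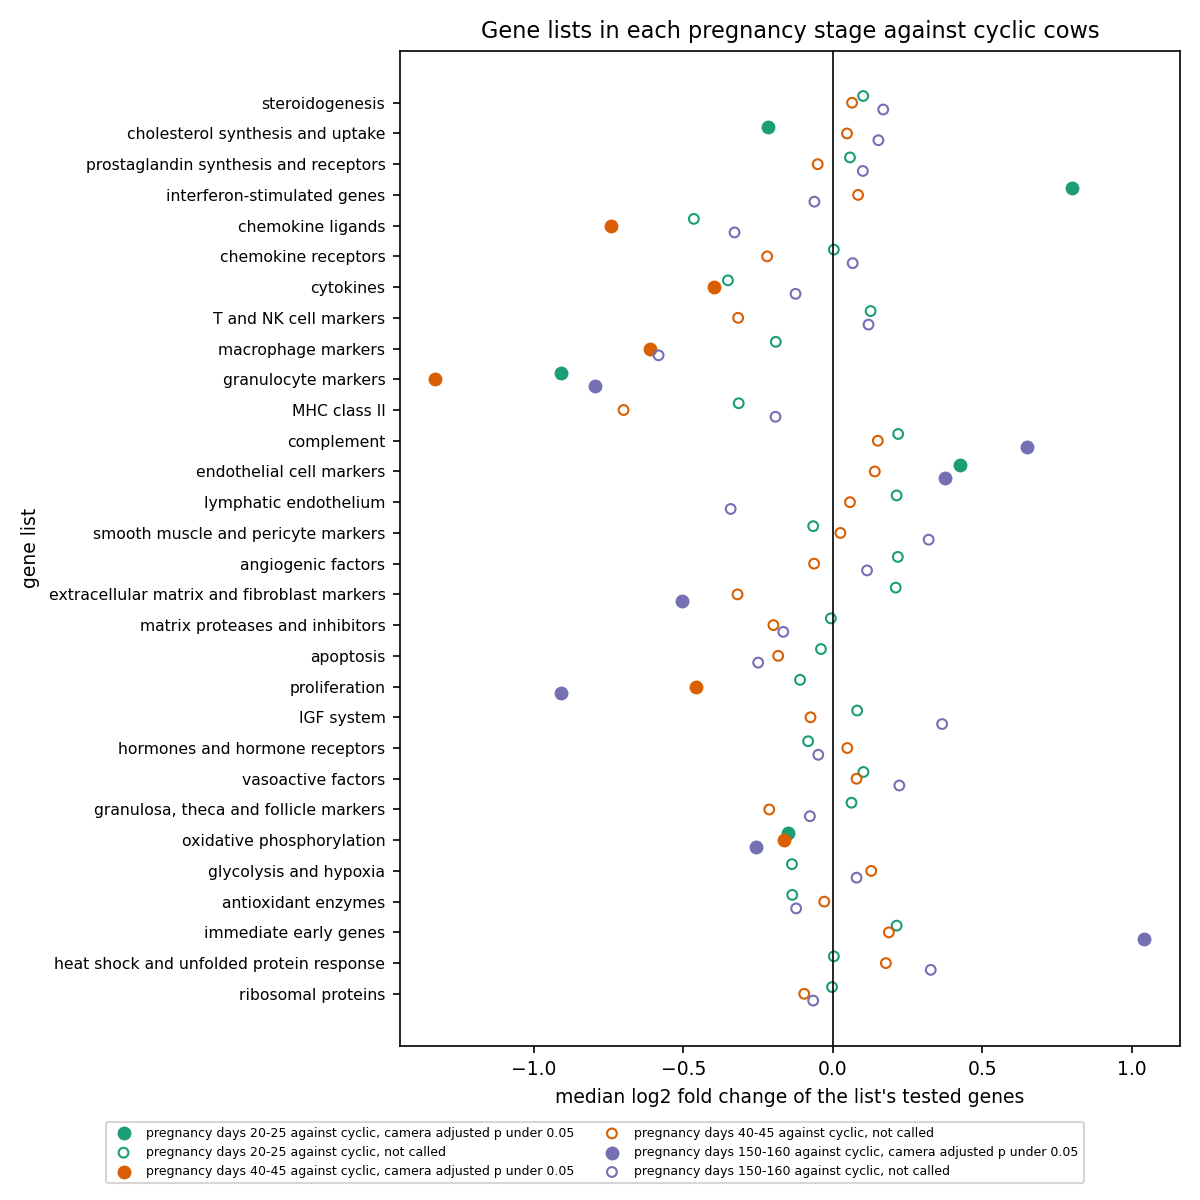
Median log2 fold change of each of the 30 gene lists in each pregnancy stage against cyclic cows, with filled points for lists that camera called with its preset correlation and open points for the rest. Granulocyte markers were lower at each stage (-0.91, -1.33 and -0.80), and interferon-stimulated genes were higher on days 20-25 (0.80).

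Of the 26 chemokine genes tested, 19 ligands and 7 receptors, the 3 that passed in at least 1 comparison with cyclic cows were CCL11, XCL1 and CXCL12. CCL11 lay at -9.22 ± 0.13 in cyclic cows, all under background, and at -6.07 ± 2.21 on days 20-25, where 3 of 4 arrays were above background and the difference was not called (adjusted p = 0.144). XCL1 lay at 0.26 ± 1.34 in cyclic cows and at -2.81 ± 0.72 on days 20-25 (adjusted p = 0.0638), before the falls on days 40-45 and 150-160. CXCL12 rose by 1.17 on days 150-160 (SE 0.29, adjusted p = 0.0264), after 0.99 and 0.79 at the earlier stages. CXCL5, a neutrophil attractant, had changes of -2.52, -2.70 and -1.10 (adjusted p = 0.133, 0.0758 and 0.371), CXCL10, an interferon-induced ligand, -1.14, -2.35 and -1.83 (adjusted p = 0.454, 0.109 and 0.116), and CXCR4, the receptor of CXCL12, -0.58, -1.20 and -1.02 (adjusted p = 0.417, 0.081 and 0.0636). GRO1 and CXCL8, neutrophil attractants, varied widely among cyclic cows, with SDs of 2.23 and 2.48, and were not called. CCL2, a monocyte attractant, had changes of -0.61, -0.44 and 1.19, and CCL5 0.46, 0.20 and 0.42. CCL8 had -0.52, -2.18 and -0.62, and CCL24 0.86, 1.68 and 1.94. Within slides 1 and 2 the change of XCL1 was -5.43 and -1.41 on days 40-45 and -5.35 and -2.78 on days 150-160. Within slide 2 it was not called at either stage (limma adjusted p = 0.619 and 0.163). With slide as a block the adjusted p of CCL11 and XCL1 on days 150-160 were 2.62e-05 and 0.00299.

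**Figure D4:**
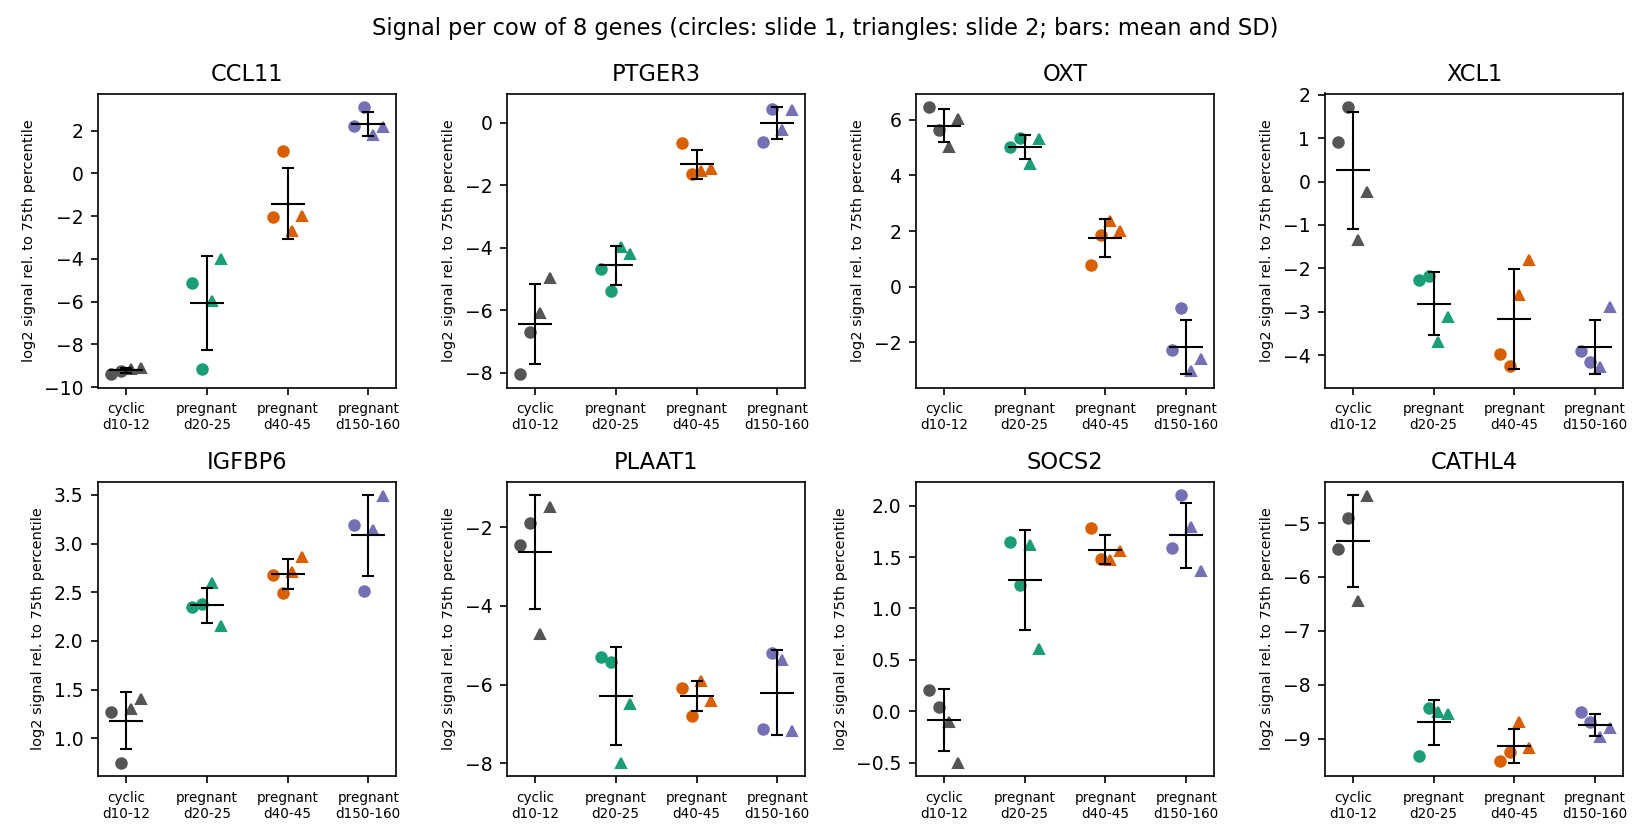
Level of 8 genes in each cow, as log2 signal relative to the 75th percentile of the array, by group, with circles for slide 1, triangles for slide 2 and bars for mean and SD. CCL11 lies between -9.39 and -9.08 in cyclic cows and between 1.79 and 3.11 on days 150-160, and OXT between 5.04 and 6.47 and between -3.03 and -0.77.

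The progesterone synthesis genes STAR, CYP11A1 and HSD3B1 and the receptor gene LHCGR showed no called difference from cyclic cows at any stage. STAR, which moves cholesterol into mitochondria, lay at 7.31 ± 0.66 in cyclic cows, with changes of 0.29, 0.27 and 0.31 (SE 0.25 each) and adjusted p of 0.61, 0.704 and 0.498. CYP11A1, which cleaves the cholesterol side chain, had changes of -0.03, 0.07 and 0.18, and HSD3B1, which forms progesterone, -0.08, 0.40 and 0.41. LHCGR, the luteinizing hormone receptor, had -1.07, -0.79 and 0.09 (adjusted p = 0.257, 0.395 and 0.919). The 14 steroidogenesis genes had medians of 0.10, 0.06 and 0.17 on days 20-25, 40-45 and 150-160, with 1 higher and 1 lower on days 150-160, over all genes and adjusted over the list alone.

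In the same order of stages, T and NK cell markers had medians of 0.13, -0.32 and 0.12, MHC class II genes -0.32, -0.70 and -0.19, and chemokine receptors 0.00, -0.22 and 0.07. Prostaglandin genes had 0.06, -0.05 and 0.10, hormones and their receptors -0.08, 0.05 and -0.05, the IGF system 0.08, -0.08 and 0.37, and vasoactive factors 0.10, 0.08 and 0.22. Lymphatic endothelium had 0.21, 0.06 and -0.34, smooth muscle and pericyte markers -0.07, 0.03 and 0.32, and angiogenic factors 0.22, -0.06 and 0.11. Matrix proteases and inhibitors had -0.01, -0.20 and -0.17, apoptosis genes -0.04, -0.18 and -0.25, and granulosa, theca and follicle markers 0.06, -0.21 and -0.08. Glycolysis and hypoxia genes had -0.14, 0.13 and 0.08, antioxidant enzymes -0.14, -0.03 and -0.12, heat shock and unfolded protein response genes 0.00, 0.18 and 0.33, and ribosomal proteins 0.00, -0.10 and -0.07. These 18 lists, steroidogenesis included, were not called by camera in any of their 54 tests, with adjusted p between 0.0642 and 0.995. The 18 calls of the other 12 lists were made with the preset correlation, and 0 held with an estimated correlation, which gave the highest adjusted p of 36 alternatives for each call; the lowest lay between 3.98e-19 for interferon-stimulated genes on days 20-25 and 0.00704 for chemokine ligands on days 40-45. With slide as a block 17 of the 18 calls stood, within slide 1 16 and within slide 2 14. The median, mean and test direction differed in sign in 15 list tests, of which 0 were called. B and plasma cell, mast cell and red blood cell lists had 4, 2 and 2 tested genes, too few for a test.

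Between pregnancy stages OXT fell at each step, and more probes differed between the earliest and the latest stage than between neighbouring stages. From days 20-25 to days 40-45 OXT changed by -3.27 (SE 0.46, adjusted p = 0.0209) and PTGER3 rose by 3.23 (SE 0.51, adjusted p = 0.0444). From days 40-45 to days 150-160 OXT changed by -3.92 (adjusted p = 0.00475), CLDN10 rose by 2.99 (adjusted p = 0.00627), NEFM at least 8.13-fold (adjusted p = 0.0141) and PYCARD, an inflammasome adaptor, by 1.88 (adjusted p = 0.0277). From days 20-25 to days 150-160 OXT changed by -7.19 (adjusted p = 1.44e-06), and CCL11, ANXA8L1 and PTGER3 rose by 8.40, 5.43 and 4.56 (adjusted p = 0.000369, 0.00382 and 0.00048), CLDN10 at least 7.72-fold and NEFM at least 7.25-fold. Over that interval CLEC12B, a C-type lectin receptor, changed by -3.40, COL1A2 by -3.07, SPON1, the matrix protein spondin 1, by -3.06 and MEST, an imprinted gene, by -3.03 (adjusted p = 0.0339, 0.00223, 0.00785 and 0.00346). ESR2 was also called lower on days 40-45 than on days 20-25 (adjusted p = 0.0209), but was not well above background on any array of either group, so no fold is given.

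These tests called 4 probes for days 40-45 against days 20-25, 2 higher and 2 lower, 5 for days 150-160 against days 40-45, 3 higher and 2 lower, and 187 for days 150-160 against days 20-25, 76 higher and 111 lower. The same order of comparisons gave 7, 13 and 247 with slide as a block, 0, 1 and 3 within slide 1, and 0, 0 and 7 within slide 2. At an unadjusted p under 0.05 limma gave 1004, 1101 and 1654 probes. The first count was 8 without cyclic replicate 1, 2 without cyclic replicate 3, 1, 0, 2 and 0 without days 20-25 replicates 1 to 4, 0, 0, 2 and 0 without days 40-45 replicates 1 to 4, and 2 without any 1 array of days 150-160. The second was 14 and 8 without cyclic replicates 1 and 2, 8 and 10 without days 20-25 replicates 2 and 4, 2, 3 and 3 without days 40-45 replicates 1, 3 and 4, and 8, 19 and 2 without days 150-160 replicates 2, 3 and 4. The third was 88 without days 20-25 replicate 1, 97 without days 20-25 replicate 2 and 101 without days 150-160 replicate 2. After normexp with the 75th percentile the higher share of the third was 50.6% in place of 40.6%. Every named call between days 40-45 and days 20-25 was lost without some single array. So were those of NEFM and PYCARD between days 150-160 and 40-45, and that of CLEC12B between days 150-160 and 20-25. The highest adjusted p of these calls lay between 0.0853 for NEFM and 0.19 for PTGER3.

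Many of the same probes were called at more than 1 stage against cyclic cows. In the same direction 130 probes were called in at least 2 of the 3 comparisons and 16 in all 3, among them CATHL1, CATHL3, CATHL4, BNBD-5, CHGB and PLAAT1, which were lower, and FGF1, SOCS2, IGFBP6, SLC26A10 and LMCD1, which were higher. Days 20-25 and 40-45 shared 18 probes, days 20-25 and 150-160 shared 26, and days 40-45 and 150-160 shared 118, with 0 in opposite directions. Because the comparisons share the cyclic arrays, 100 simulations of unchanged groups were run. In each, the 3 comparisons shared 4 simulated cyclic arrays, drawn from the residuals of all 16 arrays and not from the cyclic arrays alone. The median SD was 0.302 in cyclic cows against 0.248, 0.207 and 0.305 at the 3 stages. The simulated correlations and covariances can therefore understate what sharing the real cyclic arrays gives. The simulations shared 0 probes, a value that leaves out all effects and so gives no expected overlap among called probes. Independent lists would share 0.14, 1.2 and 3 higher and 0.063, 0.3 and 2.8 lower probes. With the cyclic arrays split into 2 and 2 the median shared number was 4.5, 8.5 and 30. Each comparison then had 2 cyclic arrays in place of 4, which by itself can lower the number of calls. These numbers therefore do not give the part of the overlap due to shared arrays. The fold changes correlated at 0.67, 0.6 and 0.78 over probes, against 0.46, 0.49 and 0.46 simulated. Their covariances were 0.16, 0.174 and 0.25, against mean simulated values of 0.051, 0.054 and 0.051, and the highest simulated values were 0.161, 0.132 and 0.132. The overlap of 130 was 191 with slide as a block and 46 and 9 within slides 1 and 2. It was 65, 200 and 68 without cyclic replicates 2, 3 and 4, 85 and 81 without days 20-25 replicates 1 and 2, and 68, 62 and 78 without days 40-45 replicates 1, 2 and 3.

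**Figure D5:**
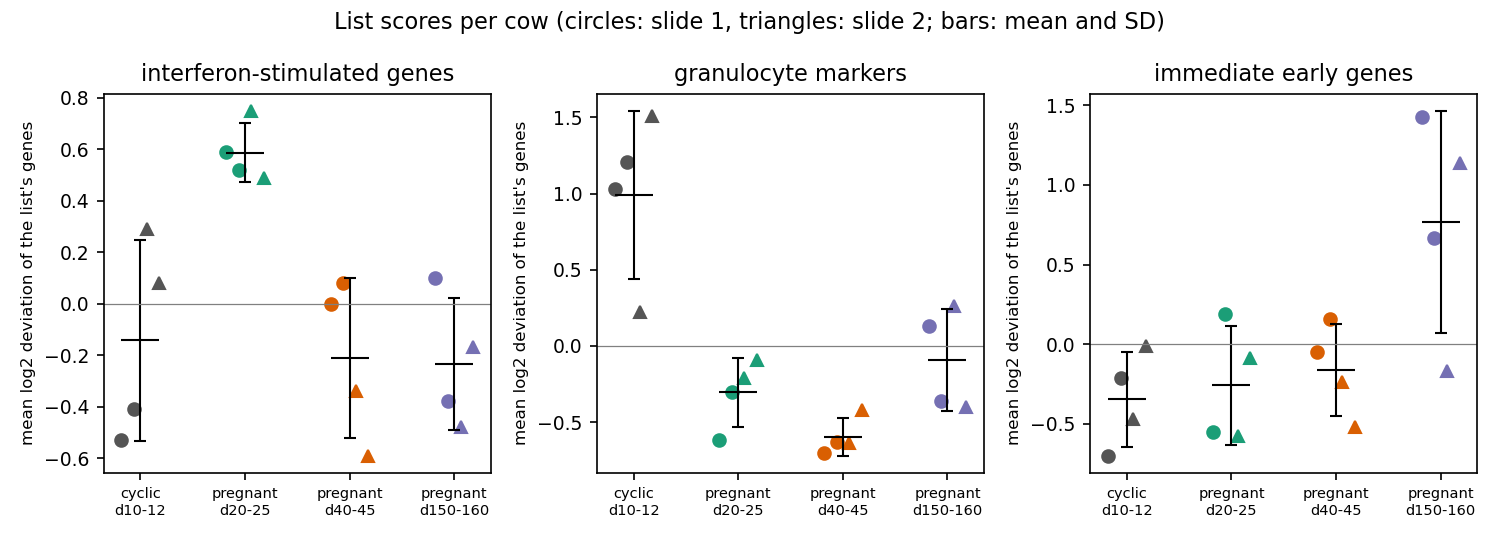
Mean log2 deviation of the genes of 3 lists from their mean over all arrays, in each cow by group, with circles for slide 1, triangles for slide 2 and bars for mean and SD. The interferon-stimulated score of days 20-25 was 0.73 above that of cyclic cows, the granulocyte score of all pregnant cows was -1.32 relative to cyclic cows (-0.78 with values under background raised to it), and the immediate early score of days 150-160 was 1.12 above that of cyclic cows.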

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

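The splits of the arrays and the question of array position were set before the results were seen, and the tests of the choice among the gene lists, immune cells, slide, granulocyte number, single arrays and stress were chosen after, as was raising values under background in the granulocyte scores. Replicate numbers below name arrays within a group.

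Interferon-stimulated genes were higher on days 20-25 than in cyclic cows, with a list score difference of 0.73. Of the 35 splits of the 8 arrays 1, the real one, gave this list a difference as large, against 0.63 for the highest other (exact permutation p = 0.0286, the smallest possible). The list was singled out among 30 by its small p, and allowing for this choice among the gene lists, 10 of 35 splits gave some list a score difference as large, up to 1.14, and 4 of 35 gave some list a camera p as small, so chance is not excluded. Slide as the only source is argued against by list medians of 1.15 and 0.44 within the slides, each of which held both groups. The size of the rise differed with slide, however. The cyclic list scores were -0.53 and -0.41 on slide 1, and 0.29 and 0.08 on slide 2. At the later stages the list went opposite ways on the slides. A part of slide in the size of the rise therefore stays open. More T and NK cells or macrophages may contribute. The interferon score minus the immune cell score differed by 0.70, close to 0.73 (exact permutation p = 0.0571). T and NK cell markers had a median of 0.13 and macrophage markers -0.19, neither called by camera. So no rise of these cells was called, but the permutation p leaves this open. Array position cannot be told apart from group, since 0 positions were held by both. The age of the gland also differed with group. Pregnancy itself stays an open, untested explanation.

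Granulocyte markers were lower in pregnant than in cyclic cows, with a score difference of -1.32 (exact permutation p = 0.0011). The groups overlapped, with cyclic replicate 3 at a score of 0.22 and days 150-160 replicate 3 at 0.26. Of the 1820 splits of the 16 arrays into 4 and 12, 2 gave a difference as large, and the highest other was 1.34 in size. Allowing for the choice among the gene lists, 2 of 1820 splits gave some list a difference as large. Several members lay under background in pregnancy, and with values under background raised to it the difference was -0.78. On that basis 67 of 1820 splits gave some list a difference as large, up to 1.14. This allows for the choice of list, but not for the several patterns singled out or the floor chosen after the results. Chance is therefore not firmly excluded. The calls by camera did not rest on a single array: the highest adjusted p of the list without any 1 array, with the preset correlation, was 0.008719. Fewer granulocytes in the tissue may account for it but cannot be told apart from lower expression: 6 cathelicidins changed by -1.69 (exact permutation p = 0.000549) and 4 other markers by -0.78 (exact permutation p = 0.00604), a difference of -0.90 with the smallest p that permutations can give, 0.000549. The cathelicidin values rest in part on signals under background: with these raised to it the changes were -0.81 and -0.74, a difference of -0.07 (exact permutation p = 0.647), so a larger fall of the cathelicidins is not shown. The other markers can also come from other cells, which keeps this open.

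Immediate early genes were higher on days 150-160 than in cyclic cows, with a score difference of 1.12 (exact permutation p = 0.0571). Of the 35 splits 2 gave a difference as large, with 1.19 for the highest other, and the number was again 2 with the choice among the gene lists allowed for, so chance is not excluded. The call by camera did not rest on a single array: its highest adjusted p without any 1 array, with the preset correlation, was 0.004681. The groups overlapped, with days 150-160 replicate 3 at a score of -0.17, between the lowest and highest cyclic scores of -0.7 and -0.01. A general stress response during tissue collection may contribute, since the heat shock score was 0.29 higher (exact permutation p = 0.0571), and this stays open. Array position cannot be told apart from group, with 0 positions held by both, and the age of the gland differed with group too. Stage of pregnancy was not tested apart from either.

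Other splits of the same arrays were counted for each number of calls. For days 20-25, 40-45 and 150-160 against cyclic cows, 35, 147 and 953 probes were called by limma. Each time 1 of 35 splits, the real one, called as many, and the highest other splits called 2, 2 and 7. This argues against chance for each comparison taken alone. A share of 1 of 35 is the smallest these splits can give, and no allowance was made for the number of comparisons. Between stages 4, 5 and 187 probes were called, again with 1 of 35 splits as large, and the highest others were 1, 2 and 2. For any difference among groups 460 probes were called, 1 of 100 drawn splits called as many, and the highest other called 70. The numbers of lists called, 5, 6 and 7, were reached by 19, 18 and 21 of 35 splits, with 11, 12 and 14 in the highest other, so chance is not excluded for them. The split that follows the slides called 0 probes and 4, 4 and 9 lists.

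A difference between stages was found by limma's own test of that difference for 4 probes between days 40-45 and 20-25, 5 between days 150-160 and 40-45, and 187 between days 150-160 and 20-25.

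Arrays far from the others of their group were sought with Dixon's ratio of gap to range, in 570 groups of 4 values. Of these 44 (7.7%) passed the critical value, where chance gives about 1 in 20. Replicate 4 of days 20-25 stood apart in its mean correlation with its group (0.889), and replicate 3 of days 40-45 in the share of probes well above background (0.892). Among cyclic cows the ratio was 0.917 for SLC26A10, 0.891 for CCL24, 0.942 for EIF2AK2, 0.941 for ATP5MC1, 0.848 for NDUFS7, 0.837 for SERPINA1, 0.911 for ADAMTSL3, 0.885 for IL16, 0.937 for AURKB, 0.976 for ASIP, 0.897 for IGFBP2, 0.916 for NEFM, 0.88 for THRA, 0.913 for PGLYRP1 and 0.944 for ESR2. On days 20-25 it was 0.876 for KCNT2, 0.97 for CCR8, 0.923 for CXCR4, 0.927 for CCL2, 0.894 for CATHL4, 0.969 for ASIP, 0.834 for DAPL1, 0.902 for THRA, 0.897 for FN1 and 0.889 for IGF2. On days 40-45 it was 0.905 for IFITM3, 0.847 for CCL21, 0.9 for CCL14, 0.833 for CCL3, 0.946 for PRPS1, 0.858 for PTGER3, 0.86 for CCNB2 and 0.86 for MEST. On days 150-160 it was 0.846 for SLC26A10, 0.881 for WASL, 0.862 for UPK1B, 0.884 for NDUFA2, 0.836 for AURKB, 0.865 for DAPL1, 0.895 for DUSP1, 0.886 for SLCO2A1 and 0.846 for PYCARD.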

How the results depend on the processing

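The alternative with slide as a block and without replicate 4 of days 20-25 was chosen after seeing the data; all others given here were planned. Values of named genes and lists under alternatives other than leaving out an array were set against the main ones. A value counted as reversed when its direction changed and it passed in either setting. Where neither passed, direction was not compared, so a change of sign there counts as kept. Of the gene values 3703 kept their side of the threshold, 47 came to pass it, 338 no longer passed and 2 reversed. Of the list values 1715 kept their side, 31 came to pass, 44 no longer passed and 4 reversed. For days 20-25, 40-45 and 150-160 against cyclic cows, days 40-45 against 20-25, days 150-160 against 40-45 and days 150-160 against 20-25, in this order, limma called 4, 34, 277, 0, 3 and 55 probes at an adjusted p under 0.01, 138, 288, 568, 219, 25 and 708 with array weights, 2, 73, 314, 7, 1 and 118 with the compared groups alone, 3, 51, 250, 0, 1 and 3 on slide 1, and 6, 12, 21, 0, 0 and 7 on slide 2, where fewer arrays were tested. The alternative chosen later gave 16, 291, 1459, 0, 18 and 171. At an unadjusted p under 0.05 and at least 2-fold the numbers were 324, 495, 770, 180, 207 and 460. With slide as a block they were 78 for days 20-25 against cyclic, 7 for days 40-45 against 20-25 and 13 for days 150-160 against 40-45. Counted as genes they were 18, 89 and 471 against cyclic cows and 10 for days 150-160 against 40-45. Without a filter on dim probes they were 90 for days 40-45 against cyclic, 8 for days 40-45 against 20-25 and 17 for days 150-160 against 40-45, and with a filter on every array 1 and 2 for the latter pair. Normexp with the 75th percentile gave 94 for days 40-45 against cyclic, and at least a 2-fold change 512 for days 150-160 against cyclic. For days 150-160 against 40-45 the authors' value table gave 9, the floor 9, and normexp with quantile normalization 12. The share higher was 50% for days 40-45 against 20-25, and 80%, 66.7% and 66.7% with quantile normalization and both normexp settings; it was 60% for days 150-160 against 40-45, and 83.3% and 85.7% with the latter settings. The F test called 119 at an adjusted p under 0.01, 904 with array weights, 42 on slide 1 and 12 on slide 2. The overlap of calls was 29 at an adjusted p under 0.01, 223 with array weights, 83 with normexp and the 75th percentile, 47 with the compared groups alone, 46 and 9 on slides 1 and 2, 238 in the alternative chosen later and 409 at an unadjusted p under 0.05 and at least 2-fold; with split cyclic arrays the pairs shared 4.5, 8.5 and 30. Of 18 list calls camera with an estimated correlation made 0; fry made 6 calls, 5 of them among the 18. Interferon-stimulated genes went opposite ways on the slides, with medians of 0.56 and -0.456 within slides 1 and 2 on days 40-45 (adjusted p = 2.924e-06 and 3.584e-05) and 0.344 and -0.42 on days 150-160 (adjusted p = 0.01838 and 0.002257). Within slide 2 proliferation genes on days 40-45 0.231 (adjusted p = 0.4913) and T and NK cell markers on days 150-160 -0.271 (adjusted p = 0.02636). With the floor PLA2G4A and ESR2 on days 150-160 had changes of 0.06 and 0.057 (adjusted p = 0.8956 and 0.8962), because their values in pregnancy lay under it and were raised. Leaving out 1 array gave 4 to 85, 63 to 226, 580 to 1106, 0 to 8, 2 to 19 and 88 to 243 calls in the order above, 267 to 503 in the F test, 62 to 200 in the overlap and 16 to 24 lists. The labels give separate animals, and the deviations do not settle whether the replicate numbers carry a pairing. Of 24 same-numbered pairs of arrays 9 had a correlation of deviations over 0.1 (0.001 to 0.291), and 9 of 16 arrays were closest to their own number. The mean correlation was 0.108 for the same number, 0.064 for another number on the same slide and -0.086 across slides. Same-numbered arrays share a slide, so slide enters these values. With the replicate number as a block the calls were 39, 199, 1087, 0, 14 and 213, with 562 in the F test, 174 in the overlap and 20 lists. Except where stated the cause was not tested. Signal over background limits falls to under background to a bound.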

Other observations

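The list tests between stages and the choice of probes without a gene name were made after the results were seen. Between stages of pregnancy camera called 10, 9 and 7 of 30 lists for days 40-45 against 20-25, days 150-160 against 40-45 and days 150-160 against 20-25, and 0 with an estimated correlation. Interferon-stimulated genes, higher on days 20-25 than in cyclic cows, were lower on days 40-45 than on days 20-25 (median -0.78, adjusted p = 4.467e-12; adjusted p = 0.4855 with an estimated correlation) and on days 150-160 than on days 20-25 (median -0.84, adjusted p = 7.369e-10; adjusted p = 0.4855 with an estimated correlation). Genes of cholesterol synthesis and uptake were higher on days 40-45 and 150-160 than on days 20-25, with medians of 0.28 and 0.44 (adjusted p = 0.0003183 and 0.0006017; adjusted p = 0.5907 with an estimated correlation for both). The level of days 20-25 was not stable: against cyclic cows the median was -0.22, and -0.07 with slide as a block and without replicate 4 of days 20-25 (adjusted p = 0.2622). That call was also lost without cyclic replicate 1 or 4 or days 20-25 replicate 1. The list tests between stages were not run without single arrays. Matrix and fibroblast markers were lower at each later stage than at each earlier one, with medians of -0.33, -0.41 and -0.70 (adjusted p = 0.003956, 4.898e-05 and 8.27e-08; adjusted p = 0.6448, 0.5907 and 0.4855 with an estimated correlation). Immediate early genes were higher on days 150-160 than on days 40-45 and 20-25, with medians of 0.96 and 1.00 (adjusted p = 2.938e-06 and 1.747e-06; adjusted p = 0.4855 with an estimated correlation for both).

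The largest rise on days 20-25 was that of a probe without a gene name, ABR8800, which the array design annotates as a clone. Its level was -1.62 ± 1.34 in cyclic cows and 5.54 ± 0.59, 5.08 ± 0.24 and 4.64 ± 0.63 on days 20-25, 40-45 and 150-160 (n = 4 cows each), 143-fold, 104-fold and 76.4-fold higher, with limma adjusted p of 9.69e-06, 2.44e-05 and 1.23e-05. The highest cyclic value was 0.33 and the lowest pregnant value 3.72.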
